A study of Mus musculus with 2 samples.

How the data were processed

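RNA was sequenced from the cerebellum of C57BL/6 mice at postnatal day 3, from a control with floxed Prdm16 alleles (Prdm16fl/fl) and from a conditional Prdm16 knockout (cKO). The labels describe total RNA made into Illumina TruSeq libraries. They name neither the Cre driver nor the deleted exons, and they give no sex. The design text speaks of triplicates, but the 2 labelled samples correspond to 1 column of read counts per genotype. Each column was treated as 1 library. The name of the deposited comparison carries a number after each genotype, which may denote numbered samples. Whether a column holds 1 library or a pool is not stated in the sources used here.

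The deposited table holds raw counts of reads per gene, per the file headers, for 22423 genes identified by Ensembl gene IDs. The submitters' processing notes name TopHat2 2.0.12, Bowtie2 2.2.3, HTSeq 0.6.0 and the mouse build mm9, without saying what each was used for. Strand use during counting is not given in the sources used here. No listed gene had fewer than 2 reads over both libraries. The deposited normalized values were on the CPM scale (reads scaled to the library total). All 44846 of these 44846 values equalled the count times 1 factor per column within a relative tolerance of 0.0001, with a count of 0 replaced by 0.5. The factors imply totals of 18604130 reads for the control and 17504235 for the cKO, 3831 and 2956 more than the listed genes hold. The authors' fold change was the ratio of the normalized values for all 22423 genes, and the authors' log2 column was its logarithm.

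The deposited p-value column came with an adjusted p, and the tool that made them is not given in the sources used here. Checked were 9535 genes with at least 200 reads and p below 0.5, without those of the smallest p-values, such as Ttr and Xist. For 99.9%, the logarithm of the deposited p-value lay within 10% of that from a normal test of 2 proportions on the 2 counts. Such a test compares the 2 libraries and not the genotypes. The adjusted values in the authors' deposited table were a median of 0.741 times the Benjamini-Hochberg values (range 0.737 to 0.747). Columns left unused numbered 0.

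The counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. Scaling factors were 1.01 for the control and 0.990 for the cKO. Further computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of the genes, 18787 had at least 10 reads over both libraries and were compared, and 3636 fell below that minimum. A gene was counted as higher or lower when the scaled ratio was at least 2-fold and its exact binomial (Clopper-Pearson) 95% interval excluded 1. A count of 0 stood at a floor of 3 counts per library, equal to 0.160 CPM in the control and 0.173 CPM in the cKO, so that its fold is a bound before the counting error of the other library, which the exact interval adds. CPM values carry exact Poisson 95% intervals. Intervals and floors cover counting error only and treat reads as independent. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that error. With 1 library per genotype there is no replicate check of any difference, no test across genes and no p-value other than the authors'.

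Gene lists were compared by the median log2 ratio of their measured members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its percentile was below 2.5 or above 97.5. The sample groups, the thresholds, the alternative settings, the rule for named genes and 32 lists with 512 genes were fixed before the data were examined. The lists were the SHH-GLI pathway, SHH target genes, Hox genes, granule neuron progenitors, postmitotic granule neurons, cell cycle, Purkinje cells, GABAergic interneurons, unipolar brush cells with cerebellar nuclei, astrocytes with Bergmann glia, oligodendrocytes, microglia and endothelial with mural cells. They further held meningeal fibroblasts, choroid plexus, ependymal and ciliated cells, erythroid genes, brainstem and midbrain neurons, forebrain and olfactory neurons, the PRDM family, brown fat and mitochondrial biogenesis genes, and the TGF-beta and BMP, WNT, Notch, immediate early, p53 and interferon response genes. Synapse, oxidative phosphorylation, ribosomal protein, sex-linked and housekeeping genes completed the set. Another 6 lists were chosen after the values had been seen.

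Named genes were Prdm16, Shh, Gli1, Hoxc4, Ptch1, Mycn, Ccnd1 and Atoh1, the 10 highest and 10 lowest genes with at least 50 reads and a symbol other than a predicted-gene name, and up to 4 members per list (the 2 highest and the 2 lowest). For a tissue weighed as a source of signal, its 5 most abundant list genes were named. Any other gene was chosen after its values were seen, and some list members that the rule names are not reported here.

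Counts were simulated for the cKO against control comparison with Poisson counting error only, so they held no spread between animals. The changed genes were drawn from those with at least 50 reads. With 18851 genes, 99 of 100 genes changed 3-fold were called in the right direction. Of 100 genes changed 1.5-fold, 0 were called, and 121 of 18651 unchanged genes (0.65%) were called. Of 200 random lists in the same simulation, 9 fell outside the central 95%. Their genes were simulated independently, so this does not cover lists whose members vary together.

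Gene names came from the table. Of 22423 IDs, 22383 matched the reference names and 21427 carried an identical symbol. Dates stood in place of 24 symbols, and 15 symbols were shared by 31 entries. The reference in hand was GENCODE M21 on GRCm38, which differs from the authors' build, so no coordinates are given. Its transcripts served only to compare near-identical gene copies with BLAST 2.17.0. Alternatives tried were DESeq2 1.42.0 size factors, library totals, a TMM without erythroid, sex-linked and mitochondrial genes, other read minimums, a 1.5-fold threshold, 99% intervals, list means and unmatched random lists.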

Results

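Gene expression was measured by RNA sequencing in the postnatal day 3 cerebellum of a Prdm16fl/fl control and a Prdm16 conditional knockout (cKO) on the C57BL/6 background. Granule neuron progenitors multiply in the outer layer of the cerebellum at this age. The table gave 1 library per genotype, with 18600299 reads over genes in the control and 17501279 in the cKO, a depth ratio of 1.06. Reads fell on 22346 genes in the control and 22293 in the cKO. The mitochondrial transcript mt-Co1 was the most abundant in both, at 1.63% of control reads and 1.68% of cKO reads, and mitochondrially encoded genes took 4.61% and 5.06%. Differences are given as log2 of the cKO over the control with a 95% counting interval in parentheses, and none has a replicate check.

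The targeted gene was examined first. Prdm16 (ENSMUSG00000039410), a zinc finger transcriptional regulator of the PRDM family, was lower in the cKO library. It had 315 reads in the control and 118 in the cKO, or 16.8 CPM (14.96 to 18.72) against 6.81 CPM (5.64 to 8.16). The log2 ratio was -1.30 (-1.62 to -0.99), a 2.46-fold lower level. The deleted exons are not given, so reads over the whole gene do not separate intact from recombined transcripts. Choroid plexus transcripts were lower in the same library by a median log2 of -4.65, and sex-linked transcripts also separated the libraries. In the PRDM family list, 1 of 13 measured genes was lower by the 2-fold rule, Prdm16 itself, and 12 passed in neither direction. Mecom stood next lowest at -0.82 (-1.35 to -0.31), and Prdm8 at 0.44 (0.35 to 0.53) and Prdm6 at 0.46 (-0.02 to 0.95) were the highest. The family's median of -0.11 lay at percentile 8.60 of random lists.

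Across the transcriptome the libraries were close for most well-covered genes. Of 10160 genes with at least 500 reads, 98.0% lay within 0.5 of a log2 ratio of 0, and the robust SD was 0.17. By the 2-fold rule, 642 of 18787 genes differed (3.42%), with 228 higher and 414 lower in the cKO. Of the well-covered genes, 2 were higher, the Y-linked Eif2s3y and Kdm5d. Another 40 were lower, 8 of them on the choroid plexus list. With the choroid plexus, Hox, brainstem and sex-linked lists left out, a choice made after seeing the data, 616 genes differed, 224 higher and 392 lower. This removes listed genes only, and other genes of the same tissues remain in the count. The number depended on the read minimum, with 231 genes at a minimum of 50 reads, and on the rule, with 1161 at 1.5-fold and 413 with 99% intervals.

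**Figure D1:**
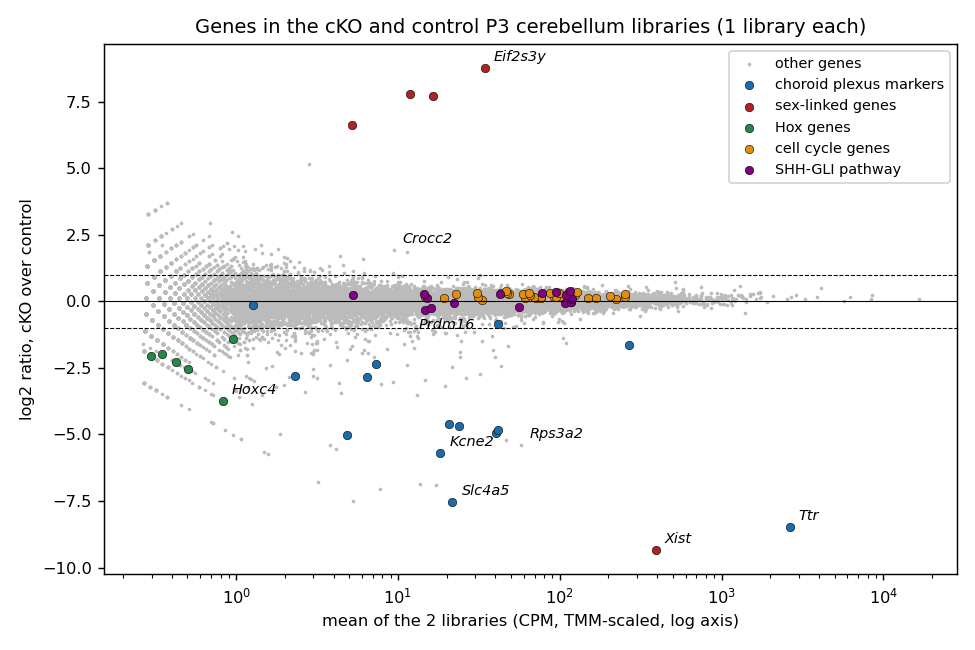
Each point is a gene with at least 10 reads, plotted by its mean level in CPM (log axis) and its log2 ratio of cKO over control, with 1 library per genotype, dashed lines at 2-fold and genes at 0 reads placed at the floor of 3 counts. Ttr lies at -8.47, Xist at -9.34 and Eif2s3y at 8.76, while the cell cycle and SHH-GLI genes lie between the dashed lines.

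The lowest named genes were Xist, Ttr, Slc4a5 and Prr32. Ttr, which encodes the thyroid hormone carrier transthyretin and is a major product of the choroid plexus, had 99032 reads in the control and 257 in the cKO, or 5269 against 14.8 CPM. Its log2 ratio was -8.47 (-8.65 to -8.30), a 355-fold lower level. The bicarbonate transporter Slc4a5 stood at -7.55 (-9.43 to -6.19) and the potassium channel subunit Kcne2 at -5.69 (-6.65 to -4.88). Prr32 (-7.51), the simple epithelial keratin Krt18 (-7.05), Tmem72 (-6.89), the frizzled-related membrane protein gene Mfrp (-6.88), Oca2 (-6.78) and the desmosomal gene Dsp (-5.74) completed the lowest 10, each with 58 to 642 control reads and 1 to 5 cKO reads. Ttr, Slc4a5 and Kcne2 were on the choroid plexus list, and these last 6 were on no list. Of 32 genes with at least 50 reads that were lower by 8-fold or more, 8 were on the choroid plexus list and 23 on no list. The choroid plexus list holds 14 genes, so a gene on no list can still come from that tissue.

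On the choroid plexus list, 12 of 14 measured genes were lower, 0 were higher and 2 passed in neither direction. The median log2 ratio was -4.65, below all of the 10000 random lists. Summed reads of the list were 114453 in the control and 3293 in the cKO, which is 0.615% and 0.0188% of all gene reads. The 2 members closest to 0 were Otx2 at -0.87 (-1.03 to -0.72) and Prlr at -0.13 (-1.04 to 0.76). Meningeal fibroblast markers, from a tissue at the brain surface, were not lower. All 14 had log2 ratios above 0, with intervals above 0 for 13, and the median of 0.25 exceeded every random list. Among them Ptgds stood at 0.53 (0.49 to 0.56), Slc6a13 at 0.52 (0.41 to 0.63), Igf2 at 0.10 (0.07 to 0.13) and Col1a1 at 0.10 (0.04 to 0.17), and none reached 2-fold.

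All 5 sex-linked genes on the list differed between the libraries. Xist, the noncoding RNA that silences 1 X chromosome in female cells, had 14779 reads in the control and 21 in the cKO, a log2 ratio of -9.34 (-10.03 to -8.73). The Y-linked genes Ddx3y (7.79, 5.92 to 10.84), Kdm5d (7.69, 6.14 to 9.97) and Uty (6.60, 4.73 to 9.66) were higher in the cKO. Eif2s3y had 0 reads in the control and 1195 in the cKO, at least 351-fold higher with the counting error of both libraries and 432-fold higher when 0 stands at the floor. The Y-linked genes summed to 7 control reads and 2352 cKO reads. On the sex-linked list, 4 of 5 genes were higher and 1 lower, with a median of 7.69 above every random list. By these transcripts the control library had a female pattern and the cKO library a male one, although the labels give no sex. Genotype and this sex pattern differed over the same pair of libraries, so no comparison here separates them.

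The series title links Prdm16 to a Shh, Gli1 and Hoxc4 axis. Gli1, the transcription factor that mediates and reports hedgehog signalling, was 1.30-fold higher in the cKO library, with 1901 and 2279 reads and a log2 ratio of 0.38 (0.29 to 0.47). Shh, the ligand made by Purkinje cells, had 92 and 99 reads and a ratio of 0.22 (-0.20 to 0.65), not distinguishable from 0 at this depth. The hedgehog receptor gene Ptch1 stood at 0.08 (-0.00 to 0.17). The proliferation genes Mycn at 0.17 (0.09 to 0.24) and Ccnd1 at 0.13 (0.05 to 0.21) were higher by small amounts, and none of these genes reached 2-fold.

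Of the 16 genes on the SHH-GLI pathway list, 0 passed the 2-fold rule, and intervals lay above 0 for 6 and below 0 for 3. Gli1 and Gli2 (0.33, 0.23 to 0.43) were the highest, and the inhibitor Hhip (-0.32, -0.57 to -0.07) and the co-receptor Cdon (-0.26, -0.50 to -0.01) the lowest. The median of 0.11 lay at percentile 97.1, inside the central range. The SHH target genes of granule neuron progenitors stood higher as a group, with 12 of 15 above 0, a median of 0.17 and percentile 99.7. Their intervals lay above 0 for 10 and below 0 for 2, with Nkx2-2 at 0.66 (0.47 to 0.86) the highest and Hhip and Ccnd2 (-0.19, -0.25 to -0.13) the lowest. Igf2 on this list was also a meningeal fibroblast marker. In the same library the housekeeping median was 0.11, the meningeal median 0.25, the choroid plexus median -4.65 and the brainstem median -0.83. None of the 15 reached 2-fold, and 1 library per genotype leaves such small shifts without a replicate spread to judge them by.

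Hoxc4 (ENSMUSG00000075394), a Hox cluster transcription factor gene, was lower in the cKO library at a low level in both. It had 29 reads in the control and 2 in the cKO, or 1.54 against 0.116 CPM. The log2 ratio was -3.74 (-6.85 to -1.76), a 13.4-fold lower level with a counting interval from 3.38-fold to 116-fold. Other Hox genes were lower too. Hoxa5 had 19 and 0 reads, Hoxa3 had 16 and 0 and Hoxa4 had 13 and 0. With the counting error of both libraries, these were at least 4.30-fold, 3.55-fold and 2.81-fold lower, and 5.84-fold, 4.91-fold and 3.99-fold lower when 0 stands at the floor. Hoxa2 stood at -1.41 (-2.69 to -0.27) with 26 and 9 reads, and Hoxb5 had 9 and 2.

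Of 39 Hox genes on the list, 11 had reads in the table, 10 of these were lower in the cKO and 6 had 0 cKO reads. The exception was Hoxd8, with 3 control and 5 cKO reads. The 11 genes together had 140 control and 19 cKO reads. By the 2-fold rule, 5 of the 6 genes with at least 10 reads were lower and 0 higher. Their median of -2.17, with the 3 genes at 0 reads placed at the floor, lay at percentile 0.01. Choroid plexus genes (median -4.65) and brainstem genes other than Hox genes (median -0.68) were lower in the same library. A minimum of 50 reads would leave out Hoxc4 and every other Hox gene. Neighbouring Hox genes can share transcripts, and how the counting assigned such reads is not given in the sources used here.

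**Figure D2:**
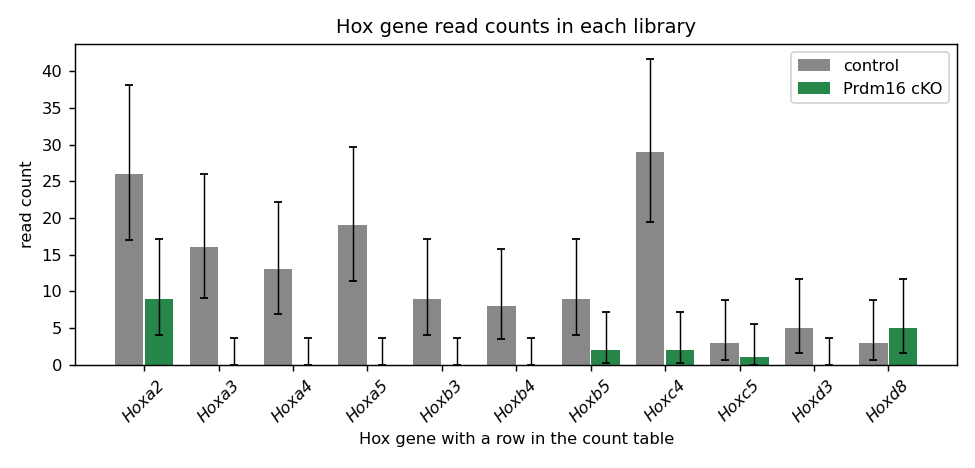
Bars give the read count of each of the 11 Hox genes with reads in the table, in the control and Prdm16 cKO libraries (1 each), with exact Poisson 95% intervals that cover counting error. Hoxc4 has 29 and 2 reads, and all but Hoxd8 (3 and 5) have fewer reads in the cKO.

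Brainstem and midbrain neuron markers were lower as a group. Of 14 measured genes, 5 were lower, 0 were higher and 9 passed in neither direction, with a median of -0.83 below all random lists. Hoxa3, also on the Hox list, was among the 5. Without Hox genes, 4 of 13 were lower, with a median of -0.68 at percentile 0.02. Th, the rate-limiting enzyme of catecholamine synthesis, had 41 and 5 reads (-2.92, -4.61 to -1.58), and the noradrenaline transporter gene Slc6a2 had 98 and 13 (-2.80, -3.76 to -1.96). Gata3 (2 and 8 reads) and Isl1 (8 and 11) were the highest, with intervals that included 0. Markers of unipolar brush cells and cerebellar nuclei were below 0 for 10 of 11 genes. Lmx1a (-1.20, -1.56 to -0.85) and Lhx2 (-1.20, -2.43 to -0.10) were lower by the 2-fold rule, and Calb2 (0.02, -0.13 to 0.16) and Eomes (-0.04, -0.16 to 0.08) were closest to 0. The list's median of -0.48 lay below all random lists, in a library where choroid plexus genes had a median of -4.65. Otx2 belonged to both of these lists.

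Proliferation genes were slightly higher in the cKO library. All 32 cell cycle genes had log2 ratios above 0, with intervals above 0 for 26, and the median of 0.19 lay above every random list. Plk1 (0.38, 0.24 to 0.52) and the replication helicase gene Mcm3 (0.36, 0.27 to 0.45) were the highest, and Cenpe (0.06, -0.11 to 0.22) and Top2a (0.08, 0.02 to 0.15) the lowest. None reached 2-fold, and the lowest median over 4 scalings was 0.16, although the scalings moved any gene by at most 0.03. In the same library the median was 0.11 for housekeeping genes, 0.25 for meningeal fibroblast markers, -4.65 for choroid plexus markers and -0.83 for brainstem markers. With 1 library per genotype, no replicate spread is at hand to judge so small a shift.

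Atoh1, the transcription factor that specifies granule neuron progenitors, was 1.53-fold higher, with 560 and 789 reads and a log2 ratio of 0.61 (0.45 to 0.77). Of 17 progenitor markers, 0 passed the 2-fold rule, 13 had ratios above 0 and the intervals lay above 0 for 11 and below 0 for 1. Nhlh1 (0.43, 0.32 to 0.53) followed Atoh1, and Ccnd2 (-0.19) and Sfrp1 (-0.08, -0.16 to 0.00) were the lowest. The median of 0.12 at percentile 95.6 did not stand apart, although the list mean of 0.15 did at percentile 99.8. Postmitotic granule neuron markers had a median of 0.10 at percentile 86.4, from Grin2c (-0.51, -0.81 to -0.22) and Unc5c (-0.09) up to Cbln1 (0.28) and Neurod1 (0.56, 0.50 to 0.62). None of their 16 measured genes passed the 2-fold rule.

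Purkinje cell, GABAergic interneuron, synapse and forebrain lists did not stand apart by their medians. Purkinje cell markers had a median of 0.12 at percentile 96.6 (99.5 at a minimum of 50 reads) and 0 of 15 genes past the 2-fold rule. Their members ran from Pcp4l1 (-0.74, -0.84 to -0.65) and Pcp4 (-0.32) to Foxp2 (0.42, 0.31 to 0.52) and Pcp2 (0.71, 0.51 to 0.90). GABAergic interneuron markers had a median of -0.04 at percentile 21.4 with 0 of 14 past the rule, from the glycine transporter gene Slc6a5 (-0.99, -1.30 to -0.68) and Sst (-0.35) to Npy (0.46) and Gsx1 (0.65, 0.34 to 0.96). Synapse genes had a median of -0.02 at percentile 6.98, with Grin2b (-0.46, -0.57 to -0.34) the lowest of 24 and Vamp2 (0.21) the highest. Forebrain and olfactory markers had 3 measured genes, a median of 0.18 and percentile 85.1.

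Glial and vascular markers did not stand apart as lists. Astrocyte and Bergmann glia markers had a median of -0.02 at percentile 6.24, with the glutamate transporter gene Slc1a2 (-0.41, -0.48 to -0.33) and Gfap (-0.41, -0.53 to -0.28) the lowest and Gdf10 (0.26) the highest. Oligodendrocyte lineage markers had a median of -0.04 at percentile 24.7, with 0 of 16 past the 2-fold rule and Cldn11 (0.26) and Enpp6 (-0.48) at the ends. For microglia the median was 0.04 at percentile 70.1 and the mean -0.02 at percentile 53.5. Among the 14 microglial genes Aif1 was higher with 23 and 47 reads (1.15, 0.40 to 1.94), and Cx3cr1 stood at -0.57 (-0.81 to -0.34). Endothelial and mural markers had a median of -0.05 at percentile 15.5, with the transporter gene Slco1c1 (-0.83, -0.98 to -0.68) the lowest of 16. Erythroid genes had a median of -0.31 at percentile 3.41, with 0 of 7 past the rule.

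Markers of ependymal and ciliated cells differed in both directions. Outside the Y-linked genes, the highest genes with at least 50 reads and a symbol other than a predicted-gene name were Znf41-ps (1.95), Crocc2 (1.92, 1.54 to 2.31), Cdhr3 (1.77), Ccdc153 (1.69, 1.16 to 2.25), Ccdc38 (1.62) and the urea transporter gene Slc14a2 (1.58). Crocc2 belongs to the ciliary rootlet protein family and had 74 and 258 reads. Znf41-ps carries a pseudogene name, and reads it shares with related zinc finger genes were not resolved. On the ependymal and ciliated cell list, Ccdc153 and Tmem212 (1.70, 0.41 to 3.18) were higher, and Gmnc, a regulator of multiciliated cell fate, was lower with 89 and 23 reads (-1.83, -2.56 to -1.16). The other 8 passed in neither direction, and Cfap126 stood at -0.77 (-1.16 to -0.39). The median of 0.30 lay at percentile 99.1, and the mean of 0.24 at percentile 97.1, inside the central range. Choroid plexus genes, from a tissue that borders the ependyma, had the median of -4.65 in this library.

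**Figure D3:**
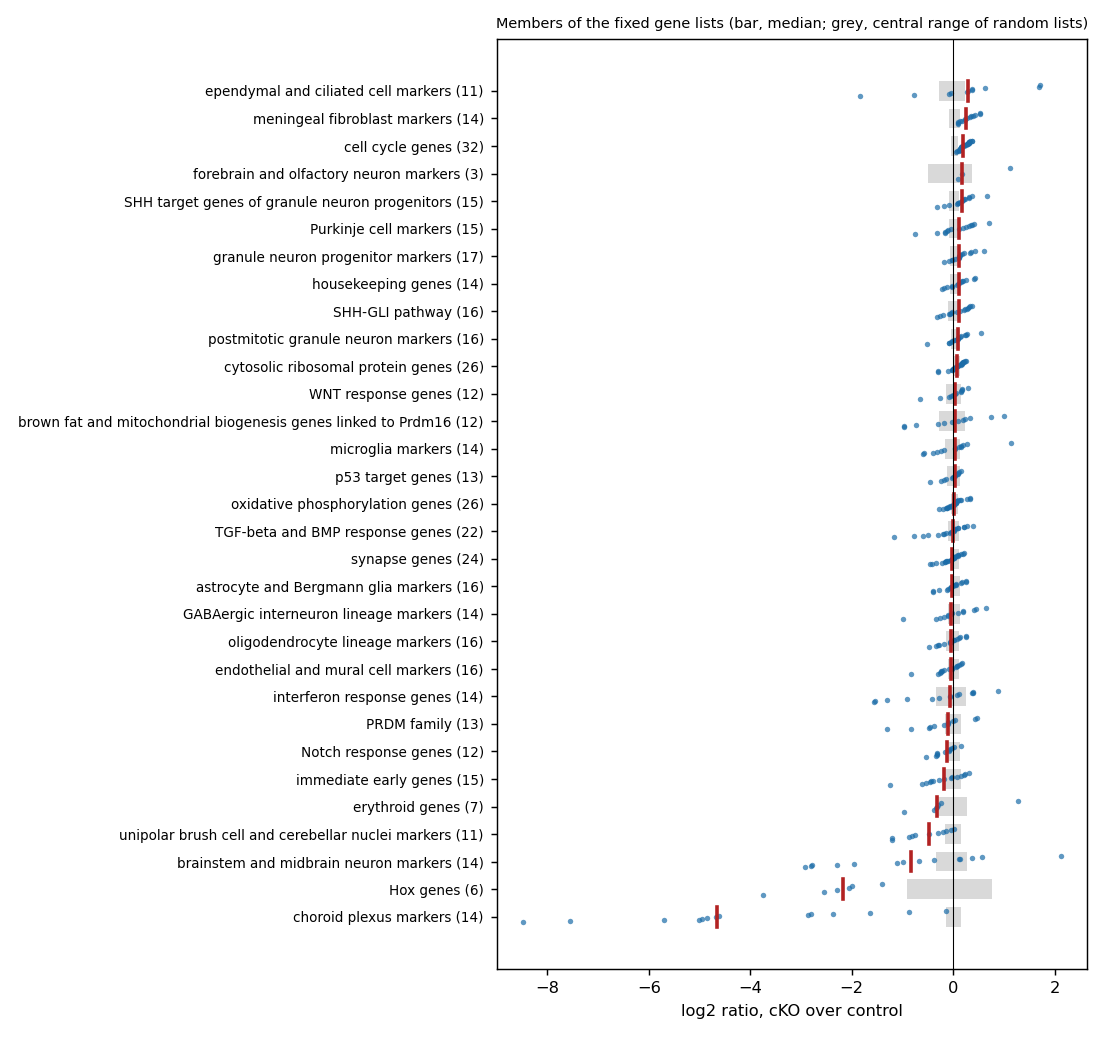
Each dot is a measured member of a gene list (number of measured members in parentheses) by its log2 ratio of cKO over control, red bars are list medians and grey boxes hold the central 95% of 10000 random lists matched on expression. The sex-linked list is left out. Choroid plexus markers have the lowest median at -4.65, followed by Hox genes at -2.17, with genes at 0 reads at the floor.

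Signalling and stress responses did not stand apart as lists. TGF-beta and BMP response genes had a median of -0.01 at percentile 37.1, and 1 of 22 was lower, the BMP target Msx1 with 764 and 314 reads (-1.16, -1.36 to -0.97). WNT response genes had a median of 0.04 at percentile 68.0 and a mean of -0.00 at percentile 56.2, with Lef1 (-0.66, -1.06 to -0.27) the lowest and Nkd1 (0.30) the highest of 12. Notch response genes had a median of -0.13 at percentile 4.59, with Notch1 (-0.54, -0.66 to -0.41) the lowest of 12. Immediate early genes had a median of -0.17 at percentile 3.81, and 1 of 15 was lower, Fosb with 36 and 14 reads (-1.24, -2.25 to -0.32). The p53 target list had a median of 0.04 at percentile 68.3 and a mean of -0.03 at percentile 37.4, with 0 of 13 past the 2-fold rule. Interferon response genes had a median of -0.06 at percentile 41.2, and Ifit1 (29 and 9 reads), Usp18 (19 and 6) and Rsad2 (24 and 9) of 14 genes were lower.

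Brown fat and mitochondrial biogenesis genes, chosen because Prdm16 is known to drive brown fat identity, had a median of 0.04 at percentile 63.9 and a mean of -0.04 at percentile 49.6. The uncoupling protein gene Ucp1 had 7 and 13 reads, Dio2 29 and 45, Cebpb 32 and 15 and Pparg 19 and 9, and 0 of 12 genes passed the 2-fold rule. Oxidative phosphorylation genes (median 0.02, percentile 35.2), ribosomal protein genes (0.09, 72.4) and housekeeping genes (0.11, 91.6) lay within the central range with 0 genes past the rule. Of the 32 lists, 9 fell outside that range, 5 above and 4 below. If the genes of a list varied independently, 1.6 would be expected. Members of a list can vary together, and some lists share genes, so the 9 cannot be judged against that number.

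The deposited comparison columns were then summarized as given. The authors' deposited table listed 4829 genes with an adjusted p under 0.05, 2027 higher and 2802 lower in the cKO. The authors' deposited table marked 622 genes as significant, 187 higher and 435 lower, which are those that also differ by at least 2-fold. Of the genes marked in the authors' deposited table, 557 were also called from the counts in the same direction, 166 higher and 391 lower. The authors' deposited table gave Prdm16 an adjusted p of 9.63e-18 and Hoxc4 one of 5.03e-06, and marked both. For Gli1 the authors' deposited table gave 2.24e-13 and for Atoh1 6.38e-12, with no mark, and for Shh 0.446. These p-values compare the reads of 2 libraries and carry no spread between animals.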

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

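The 2-fold filter on the authors' columns and the count without 4 lists were chosen after the values had been seen. Of 480 alternative values, 431 for single genes and lists stayed on their side of the threshold or inside their counting interval, and no value past the threshold changed sign. The ratio of a single gene, Prdm16 included, does not depend on the read minimum, the fold threshold or the interval width. Gene values under those settings were therefore unchanged by construction, and the 431 do not measure robustness. Another 31, counts within 1.5 times the original or the Prdm16 level within its interval, included 294 lower genes with 99% intervals, 11 lists standing apart from unmatched random lists and 6163 genes of the authors' deposited table at an adjusted p under 0.1. Among lists inside the central range, the oxidative phosphorylation median of 0.019 became -0.00040 with DESeq2 size factors and -0.011 with library totals, and the microglia, brown fat, WNT and p53 lists had means below 0 and medians above. The 642 differing genes became 231 at a minimum of 50 reads (55 higher, 176 lower), 1161 at 1.5-fold (425 higher, 736 lower) and 413 with 99% intervals (119 higher). Fewer genes or a looser or stricter rule account for these numbers by construction. The 4829 genes of the authors' deposited table became 3176 at an adjusted p under 0.01, 1026 with at least 1.5-fold and 622 with at least 2-fold. Other scalings moved any gene by at most 0.03 in log2 and gave 212 to 228 higher and 418 to 455 lower genes. Granule neuron progenitor (percentile 99.8 by the mean), Purkinje (99.5 at 50 reads) and erythroid lists (1.81 and 1.43) came to stand apart under some settings. So did the immediate early list, at 2.17 with unmatched lists and 2.195 with no minimum of reads. The ependymal list no longer stood apart by its mean (97.1). No paired analysis was possible because each genotype had 1 count column. Planned fits with replicates, pseudocounts or centred normalized values were not run for the same reason or because counts were at hand. A minimum of 50 reads left out Hoxc4 and every other Hox gene, so neither the Hoxc4 difference nor the Hox list has a value there, nor does the forebrain list. At these depths genes with few reads, Hoxc4 among them, had wide intervals.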

Other observations

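The 6 lists described first, and the tests of each pattern except the sequence comparison of gene copies, were chosen only after the values had been seen, so the percentiles of these 6 lists are not independent evidence. Noradrenergic neuron genes were lower in the cKO library, with 4 of 6 measured genes lower by the 2-fold rule and a median log2 ratio of -2.38 below all random lists. Among these were Th (41 and 5 reads), Slc6a2 (98 and 13) and Dbh (55 and 13), which makes noradrenaline. Ddc (28 and 27 reads) and the vesicular transporter gene Slc18a2 (115 and 127), shared with other monoamine neurons, were not lower. X-linked genes known to escape X inactivation were below 0 for 4 of 4 genes, with a median of -0.61 at percentile 0.02. Kdm6a was lower (-1.15, -1.36 to -0.95) and Ddx3x closest to 0 (-0.36, -0.41 to -0.30), in the library that also lacked most Xist reads.

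Mitochondrially encoded protein genes were above 0 for 12 of 12, with a median of 0.20 at percentile 99.7, from mt-Co2 (0.02, -0.07 to 0.11) to mt-Nd2 (0.51, 0.50 to 0.53) and mt-Nd6 (0.56, 0.53 to 0.59). GABA-A receptor subunit genes were below 0 for 10 of 14, with a median of -0.34 at percentile 0.02 and none past 2-fold. Gabre (-0.99, -1.83 to -0.19) was the lowest and Gabra2 (0.29, 0.07 to 0.52) the highest, while Gabrb1 stood at -0.63 (-0.84 to -0.41). NMDA receptor subunit genes, listed after Grin2b and Grin2c had been seen among the lowest members of other lists, were below 0 for 6 of 7, with a median of -0.19 at percentile 2.38, at the edge of the central range. Grin2c (-0.51), Grin2b (-0.46) and Grin3b (0.06, -0.81 to 0.93) marked the range. In the same library the medians were -4.65 for choroid plexus, -0.83 for brainstem and -0.48 for unipolar brush cell and cerebellar nuclei markers. Axonemal dynein heavy chain genes had a median of -0.01 at percentile 54.6 and a mean of 0.22, with Dnah3 (6 and 23 reads) and Dnah12 (13 and 25) higher.

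Choroid plexus genes were lower in 12 of 14 members, led by Ttr (5269 against 14.8 CPM), with Enpp2 (406 and 130 CPM), Aqp1 (79.8 and 2.77), Clic6 (78.6 and 2.54) and Otx2 (53.7 and 29.4), also on the unipolar brush cell list, next in abundance. Depth or scaling is argued against, since either would shift all genes alike, while the list's median lay at -4.75 relative to that of housekeeping genes. Trimming of meninges together with choroid plexus is argued against by the meningeal median of 0.25. A choroid plexus left out at dissection and one that did not form in the cKO are both consistent with a median residual of 3.99% of the control. As a hypothesis, loss of Prdm16 could impair choroid plexus formation, but 1 library per genotype cannot separate this from dissection. Genotype cannot be separated from the female and male transcript patterns of the 2 libraries either, and an effect of sex was not tested.

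Hoxc4 was lower along with its family. Counting error is argued against by the upper bound of -1.76 for its log2 ratio, and a change of Hoxc4 alone by the -2.59 (-3.42 to -1.85) of the other Hox genes' summed reads. More hindbrain tissue outside the cerebellum in the control sample is a candidate explanation. Its test asked only that the median of brainstem and midbrain markers other than Hox genes fall below percentile 2.5. Their median was -0.68 (percentile 0.02). Of the 13 measured, 8 were below 0 and 4 were lower by the 2-fold rule. That median is a smaller fall than the -2.59 of the other Hox genes' summed reads. The test set no size, so it does not decide whether such tissue accounts for the Hox difference. These markers do not show which tissue the Hox reads came from. Of the most abundant of these markers, Slc6a5 (14.9 and 7.51 CPM, also on the interneuron list), Slc6a2 (5.21 and 0.751) and Lbx1 (23.2 and 17.9) had lower values, while Tlx3 (41.4 and 45.2, also a granule neuron progenitor marker) and Slc5a7 (3.14 and 4.04) did not. Hoxc4 reads that came with choroid plexus tissue stay open, since the residual of 7.48% (0.865 to 29.6) includes the choroid plexus median of 3.99%. The residual of the other Hox genes, 16.6% (9.35 to 27.8), lies above that median, with most of their cKO reads from Hoxa2 (9) and Hoxd8 (5). Without Hoxa2 and Hoxd8, the other 8 genes had 82 and 3 reads. Their residual of 3.97% (0.802 to 12.02) includes the choroid plexus median. Leaving out the genes with the most cKO reads lowers the residual by construction, so these values do not decide on a choroid plexus source. An effect of Prdm16 on Hox genes remains as an untested hypothesis.

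A group of ribosomal and mitochondrial transcripts stood out, Rps3a2 (2110 and 46 reads), Rps3a3 (1712 and 43) and Ndufs5 (490 and 58). Their near-identical copies went the other way, Rps3a1 with 7257 and 11099 reads and BC002163 with 408 and 745. Summed over copies, Rps3a reads had a log2 ratio of 0.13 (0.09 to 0.17) and Ndufs5 with BC002163 one of -0.043 (-0.18 to 0.10), values that a reassignment of reads between copies needs. The lowest best identity was 98.9% over the aligned bases, which span 792 of 792 and 795 of 795 for Rps3a2 and Rps3a3 but 319 of 680 for Ndufs5. A strain variant or a difference in read processing between the libraries could move such reads, and neither was tested.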
